A study of Penicillium oxalicum with 4 samples.

How the data were processed

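Total RNA of mycelia from 4 Penicillium oxalicum strains, with 1 library each, was profiled by digital gene expression tags. Per the labels' protocols, mRNA was captured on oligo(dT) beads, double-stranded cDNA was cut with NlaIII at CATG, and MmeI cut 17 bases downstream, so that each transcript gave a tag of 21 nt. The authors trimmed the adaptors and removed low-quality tags, tags of another length and tags seen as 1 copy, per the labels' protocols. They then matched tags without mismatch to predicted transcripts extended by 300 nt, per the same protocols, but that assignment to genes was not used here. The aligner, its version and the genome build were not given in the sources used here. The deposited count column gives raw copies of each clean tag, not normalised. The deposited TPM column gives the same copies per 1000000 clean tags of the library, per the file headers, and was checked against the copies but not tested.

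The reference table used here held 9964 genes of the assembly ASM172317v3, of which 0 had a symbol other than the locus tag, and 0 columns of sequence. Tags were thus not matched to genes. The tests had been designed for genes, with the provision that tags would be tested if no sequences were at hand, and that provision was followed. The tests, thresholds, naming rule and most alternatives were chosen before the data were examined. The tag classes, the pairings of libraries, the abundant tags and the alternatives described as added were chosen after the data were seen.

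Tags with 20 or more copies summed over the 4 libraries were tested, 38039 in all, holding 90.3% to 96.0% of the copies of each library. Each of 5 pairs of libraries was compared with a two-sided exact conditional binomial test of a tag's copies given the library totals, with Benjamini-Hochberg adjustment. A tag was called where the adjusted p was at most 0.001 and the ratio of TPM at least 2 either way. Rose and fell refer to such calls only. Ratios have 95% Clopper-Pearson counting intervals and levels have exact Poisson intervals. Sequenced PCR products without molecular identifiers are not independent molecules, so intervals and bounds cover counting error only. A tag unlisted in a library was counted as 0 in the test, and its ratio was computed against a floor of 3 copies and given as a bound. Since 1 copy may have been removed, for which the upper limit is 4.74 copies, such bounds would be 1.58 times lower in that case.

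Departure from additivity was tested with an exact conditional test on the noncentral hypergeometric distribution, calling tags at an adjusted p of at most 0.001 and a log2 departure of at least 1 either way. An additive model of laeA and creA genotype was fitted over the 4 libraries with edgeR's quasi-likelihood test, trimmed-mean (TMM) scaling and an adjusted p under 0.05. It had 1 residual degree of freedom and an estimated coefficient of variation of 0.779. Overlaps of calls were set beside the number that independent lists would share, and, where the wild type was in both comparisons, beside 20 simulated draws of unchanged libraries. Expected overlaps were also computed within classes of GC content, trailing A run and abundance, taken over the 4 libraries or, as an addition, over the pair of libraries that still had the gene. In GC centring, the median log2 ratio of each GC class was used as an offset in the exact test.

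The named tags were the 2 that rose and the 2 that fell most in each comparison among those called with at least 20 TPM in the higher library, ranked with unlisted tags at the floor. The same rule was used for the departure from additivity. Any other tag named was chosen after its values were seen.

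Alternatives were TMM factors, DESeq2 size factors, leaving out tags under 5 copies, no filter, a minimum of 100 copies, edgeR's exact test with an assumed coefficient of variation of 0.2 or 0.4, a fold threshold of 4, and a log2 departure of at least 2. The additive fit was repeated with DESeq2, without a filter and without TMM factors. Library richness was repeated after thinning to the smallest total. Alternatives added were leaving out the most abundant tag, counting unlisted tags as 1 copy, adding tags 1 base away from a tag with 50 times their copies to it, and filtering without the double deletion. The fixed gene lists, the cell form markers, the check of the deleted genes and the alternatives that need gene assignment were not run, for lack of sequences to match.

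The methods were tested on simulated copies for the 38039 tags. For the exact test of pairs, counting error alone was simulated, with 88 to 112 changed tags per comparison and fold. Changed tags, also for the additive fit below, were drawn only among the more abundant tags. No recovery given here covers tags with few copies. Of tags changed 4-fold, the exact test recovered 95.0% for the laeA deletion against wild type, 94.3% for the creA deletion against wild type, 99.0% for the double deletion against wild type, 95.4% for it against the laeA deletion and 97.0% against the creA deletion. It recovered 100.0% of those changed 8-fold in each, with 1 false call in the first and 0 in the others. The additive fit, on 35780 simulated tags with a coefficient of 0.2, recovered 100.0% of 8-fold laeA changes with 5 false calls. That coefficient is below the 0.779 estimated in the data, so this recovery does not apply to the fit reported. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.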

Results

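Digital gene expression tag profiling compared mycelia of 4 strains of Penicillium oxalicum, a filamentous fungus known for secreted cellulases. The strains were the wild type 114-2, a laeA deletion, a creA deletion and a double deletion of both genes, each with 1 library. LaeA is a putative methyltransferase that regulates secondary metabolism in filamentous fungi, and CreA is the zinc-finger repressor of carbon catabolite repression. All strains grew on glucose and were sampled 48 h after transfer to new medium. The assay counts 21-nt tags, each made of a CATG site and the 17 bases that follow it in the cDNA. The libraries held 3373870 copies (wild type), 3355665 (laeA deletion), 3372790 (creA deletion) and 3388874 (double deletion), so that 1 copy corresponded to 0.295 to 0.298 TPM, the number of copies per 1000000 clean tags. Tags were analysed by sequence, without gene names, since no transcript sequences were used here. A gene can give several tags and a tag can come from several genes. The tags of laeA and creA were therefore not identified, and the deletions were not checked against the labels. With no replicate, the intervals and exact tests cover counting error only and compare libraries, not strains.

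The 4 libraries listed 197359 distinct tags, of which 32628 were found in all of them. The wild type listed 79405 tags, the creA deletion 78473, the laeA deletion 90512 and the double deletion 119691. Across tags, log2 copies of the wild type correlated most with those of the creA deletion (Pearson 0.869, Spearman 0.835), less with the laeA deletion (0.674, 0.628) and least with the double deletion (0.447, 0.390); tags are not independent replicates. The double deletion correlated with the laeA deletion at Pearson 0.456 and Spearman 0.387, and with the creA deletion at 0.411 and 0.351. The 10 most abundant tags took 13.7% of the wild-type copies, 13.0% of the laeA deletion, 15.2% of the creA deletion and 6.35% of the double deletion. The double deletion library also differed in the makeup of its tags. Tags with a second CATG held 1.13% of its copies, against 0.382% in the wild type, 0.332% in the laeA deletion and 0.509% in the creA deletion. Tags ending in a run of 8 or more A held 2.51% of its copies, against 4.83%, 7.30% and 6.09%. The GC content of its copies, without the most abundant tag, was 47.2%, against 41.9%, 41.0% and 41.6%. For shares of all copies of a library, the 95% Wilson interval reached at most 0.0535 percentage points to either side.

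A single tag, CATGCTGCTCTGTTTTTAGCT, was the most abundant of the wild type, the laeA deletion and the creA deletion. It stood at 80132 TPM in the wild type (95% exact Poisson interval 79830 to 80434), 80592 in the laeA deletion, 113575 in the creA deletion and 2951 in the double deletion. The most abundant tag of the double deletion was CATGTCGGGGCTCCAGATACA, at 11852 TPM, against 127.5 in the wild type, 125.2 in the laeA deletion and 90.7 in the creA deletion. Both tags were chosen after their values were seen.

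The comparison of the laeA deletion with the wild type addressed which transcripts depended on laeA while creA was present. Abundant tags of both libraries were replaced in part. Of the 100 most abundant wild-type tags, 62 fell and 6 rose, and of the 100 most abundant of the laeA deletion, 48 rose and 10 fell; tags chosen as highest in a library tend to be lower in any other. The 3169 tags that fell held 34.7% of the wild-type copies and 6.28% of the laeA deletion copies. The 4221 tags that rose went from 8.76% to 32.3%. The calls covered 19.4% of the 38039 tags tested.

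The tags that rose most were CATGAACCGGATTTGTCTTAC, from 2 copies to 7333, and CATGTCCCGTAATCTTTATCC, from 19 copies to 15622. The first had a log2 ratio of 11.85 (95% counting interval 9.995 to 14.89). The second was 827-fold higher, at a log2 ratio of 9.69 (9.05 to 10.42). The tags that fell most were CATGGGCTTTGCTCCGGCACG, from 6393 copies to 2, and CATGGAAATTCAAATAGCAAA, from 7038 copies to unlisted. The log2 ratio of CATGGGCTTTGCTCCGGCACG was -11.63 (-14.68 to -9.78), and CATGGAAATTCAAATAGCAAA was at least 2333-fold lower. Among the 10 most abundant wild-type tags, which were listed after their values were seen, CATGCACGGTGAAATCCAGTT fell 80.1-fold and CATGTCTCGGTCTACGCATAT 26.1-fold. The leading tag CATGCTGCTCTGTTTTTAGCT, at a log2 ratio of 0.01 (0.00 to 0.02), did not pass the test. Tags ending in a run of A rose more often than they fell, at 396 against 125 of the 2388 tested. The GC content averaged 40.1% over the tags that rose and 44.4% over those that fell, against 44.2% over all tags tested.

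Tags with 20 or more copies in both libraries had a median log2 ratio of 0.21, and the trimmed-mean scaling of edgeR shifted all ratios of this pair by -0.21. Rises made up 57.1% of the calls, but 46.2% with that scaling, 45.6% with the size factors of DESeq2 and 39.9% after centring each GC class, so the majority direction of the calls was not fixed. Of the 7390 calls, a threshold of 4-fold left 4776. A minimum of 100 copies, which tests fewer tags, gave 4719. With edgeR's exact test, an assumed biological coefficient of variation of 0.4 gave 2587 calls, but 0.2 gave 8083. That test called tags at an adjusted p under 0.05, against at most 0.001 in the main test, so its counts are at a looser threshold.

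The comparison of the creA deletion with the wild type addressed which transcripts depended on creA on glucose, the condition in which CreA acts as a repressor. This pair of libraries differed least. In total 1304 tags rose and 1346 fell, 6.97% of those tested. The tags that rose went from 4.28% to 12.7% of copies, and those that fell from 18.3% to 6.403%. Of the 100 most abundant wild-type tags, 2 rose and 30 fell, and of the 100 most abundant of the creA deletion, 18 rose and 9 fell.

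The tag that rose most, CATGTCAACAAGAATAAAACG, was unlisted in the wild type and stood at 9751 copies, at least 3251-fold higher. It was also unlisted in the laeA deletion, and had 728 copies in the double deletion. CATGATCAAGGGTGTCACTCT rose from 2 copies to 247, a log2 ratio of 6.95 (5.08 to 10). CATGCGCGCTACGAAACGATA fell from 536 copies to unlisted, at least 179-fold, and had 832 copies in the laeA deletion and 3 in the double deletion. CATGGACGGCAGAATGGACGG fell 47.7-fold, from 191 copies to 4, at a log2 ratio of -5.58 (-7.47 to -4.20). Tags ending in a run of A rose in 127 cases and fell in 39. The tags that rose had a GC content of 39.9%, and those that fell of 44.9%. The number of calls depended on the test and, within edgeR's exact test, on the spread assumed between libraries. Rises made up 49.2% of the calls, and 54.1% without the most abundant tag. With edgeR's exact test, 1620 tags were called at an assumed biological coefficient of variation of 0.2 and only 69 at 0.4. A threshold of 4-fold in the main test left 958.

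Calls of both single deletions coincided more often in the lower direction than in the higher. In both, 845 tags were lower and 499 were higher, where independent lists would share 112 and 145. Unlike for the overlaps below, no expectation within classes of abundance was computed, so the abundance of tags was not taken into account. Opposite calls were fewer than same-way calls. There were 45 tags higher without laeA and lower without creA, against 149 for independent lists, and 110 the other way, against 109. Filtering without the double deletion library gave 856 tags lower in both and 522 higher in both. Independent lists would then share 150 and 190, a smaller contrast. Of the tags named above, CATGTCCCGTAATCTTTATCC rose in both single deletions, 827-fold and 5.32-fold. CATGGGCTTTGCTCCGGCACG and CATGGAAATTCAAATAGCAAA fell in both, the former 2.20-fold and the latter 2.72-fold in the creA deletion. Because both comparisons use the same wild-type library, unchanged libraries were simulated against it, giving means over 20 draws of 0 shared calls each way with counting error alone. With an assumed coefficient of variation of 0.4, they gave 409 higher and 356 lower. Across 13370 tags the log2 ratios had a Pearson correlation of 0.373, a Spearman correlation of 0.434 and a covariance of 0.638. The simulated unchanged libraries gave a higher Pearson correlation, 0.498 with counting error alone, and covariances of 0.0572 with counting error alone, 0.145 at a coefficient of 0.2 and 0.423 at 0.4. The simulations stop at 0.4, below the coefficient of 0.779 estimated in the additive fit. That estimate includes the departures of the double deletion and is not the spread among the wild type and the single deletions. The single control library could not be split. Part or all of the excess may thus come from the shared wild-type library.

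**Figure D1:**
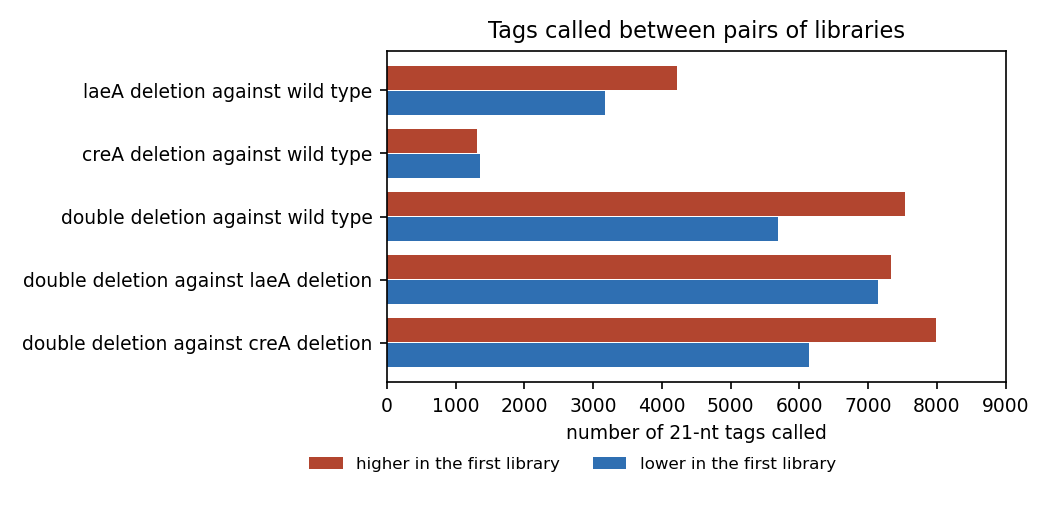
Number of 21-nt tags called higher or lower in the first-named library of each pair of libraries (horizontal axis), out of 38039 tags tested. The 3 comparisons with the double deletion have 13217 to 14473 calls, against 7390 for the laeA deletion and 2650 for the creA deletion.

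The double deletion was compared with the wild type to ask how the loss of both genes together altered the tag profile. Of the 100 most abundant wild-type tags 72 fell and 4 rose, and of the 100 most abundant of the double deletion 68 rose and 7 fell. The 5682 tags that fell held 55.0% of the wild-type copies and 9.16% of the double deletion copies. The 7535 tags that rose went from 8.12% to 49.4%. Of these, 2154 were unlisted in the wild type. The leading wild-type tag CATGCTGCTCTGTTTTTAGCT fell 27.2-fold, and CATGTCGGGGCTCCAGATACA rose 93.0-fold.

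CATGGAAACGGAAGCGTGTAC rose from 2 copies to 19096, a log2 ratio of 13.21 (11.36 to 16.26). The single deletions had 32 and 36 copies of it. CATGAACCGGATTTGTCTTAC rose from 2 copies to 14395, a log2 ratio of 12.81 (10.95 to 15.85). This tag also led the rises of the laeA deletion, while the creA deletion had 4 copies. CATGCGGATGTTCTTGCGGGC fell from 3831 copies to 2, a log2 ratio of -10.91 (-13.96 to -9.06). The laeA deletion likewise had 2 copies of it, and the creA deletion 6404. CATGTTGAGCAATAGGTCTCG fell 961-fold, from 6699 copies to 7, and was unlisted in the laeA deletion. Tags with a second CATG rose in 247 cases and fell in 41 of the 468 tested, and tags ending in a run of A rose in 91 and fell in 399. The tags that rose had a GC content of 49.96% and those that fell of 41.7%. Rises made up 57.0% of the 13217 calls, and 42.7% after centring each GC class, which left 12898 calls. A minimum of 100 copies gave 7345 calls and an assumed coefficient of variation of 0.4 gave 7713. Trimmed-mean scaling shifted all ratios by -0.11 and gave 53.2%.

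The double deletion was set against the laeA deletion to ask what differed with creA missing where laeA was already missing. Here 7336 tags rose and 7137 fell, 38.05% of those tested. The tags that fell held 54.8% of the laeA deletion copies and 10.02% of the double deletion copies. The largest rises were of tags listed in no other library. CATGTTGGAGTCTCAGAATGG had 8875 copies, at least 2929-fold higher, and CATGTTGGGGGCACAACATAC had 3516, at least 1161-fold higher. CATGCTCTGTCTTACGTGATC fell 525-fold, from 3638 copies to 7, having 302 copies in the wild type and 801 in the creA deletion. CATGGCGGCGAGAGTGAGGAG fell from 734 copies to 2, a log2 ratio of -8.53 (-11.58 to -6.68), and had 833 copies in the wild type and 1139 in the creA deletion. Tags ending in a run of A fell in 738 cases and rose in 44, and tags with a second CATG rose in 250 and fell in 47. GC content averaged 50.8% over the rises and 39.7% over the falls. Rises made up 50.7% of the calls, 57.1% with the size factors of DESeq2, 46.4% without the most abundant tag and 47.0% after centring each GC class. A minimum of 100 copies gave 7810 calls and an assumed coefficient of variation of 0.4 gave 8555.

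Differences between libraries without and with creA, in the presence and in the absence of laeA, were compared through pairs of libraries with no member in common. More tags moved in opposite ways than in the same way. Of the 1304 tags higher in the creA deletion than in the wild type, 525 were lower in the double deletion than in the laeA deletion and 144 were higher, where independent lists would share 245 and 252. Of the 1346 tags lower in the creA deletion, 399 were higher in the double deletion and 225 were lower, against 260 and 252.5. The log2 ratios correlated across tags at Pearson -0.17 and Spearman -0.21. CATGTCAACAAGAATAAAACG rose in both, by at least 3251-fold with laeA and at least 240.3-fold without it. CATGGACGGCAGAATGGACGG fell in both, 47.7-fold with laeA and 6.87-fold without it.

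The double deletion was set against the creA deletion to ask what differed with laeA missing where creA was already missing. In this pair 7987 tags rose and 6134 fell, 37.1% of those tested. Of the 100 most abundant tags of the creA deletion, 71 fell and 4 rose, and of the 100 most abundant of the double deletion, 68 rose and 4 fell. CATGAACCGGATTTGTCTTAC rose from 4 copies to 14395, 3582-fold, at a log2 ratio of 11.81 (10.45 to 13.68). CATGTTGGAGTCTCAGAATGG was at least 2944-fold higher. CATGCGGATGTTCTTGCGGGC fell from 6404 copies to 2, a log2 ratio of -11.65 (-14.70 to -9.80). CATGAACAGTTAAAAAAAAAA fell from 4560 copies to unlisted, at least 1527-fold, and was likewise unlisted in the laeA deletion against 1643 copies in the wild type. Tags ending in a run of A fell in 621 cases and rose in 54, and tags with a second CATG rose in 258 and fell in 56. The GC content was 50.3% over the rises and 40.4% over the falls. Rises made up 56.6% of the calls, and 42.4% after centring each GC class. A minimum of 100 copies gave 7631 calls and an assumed coefficient of variation of 0.4 gave 9015.

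**Figure D2:**
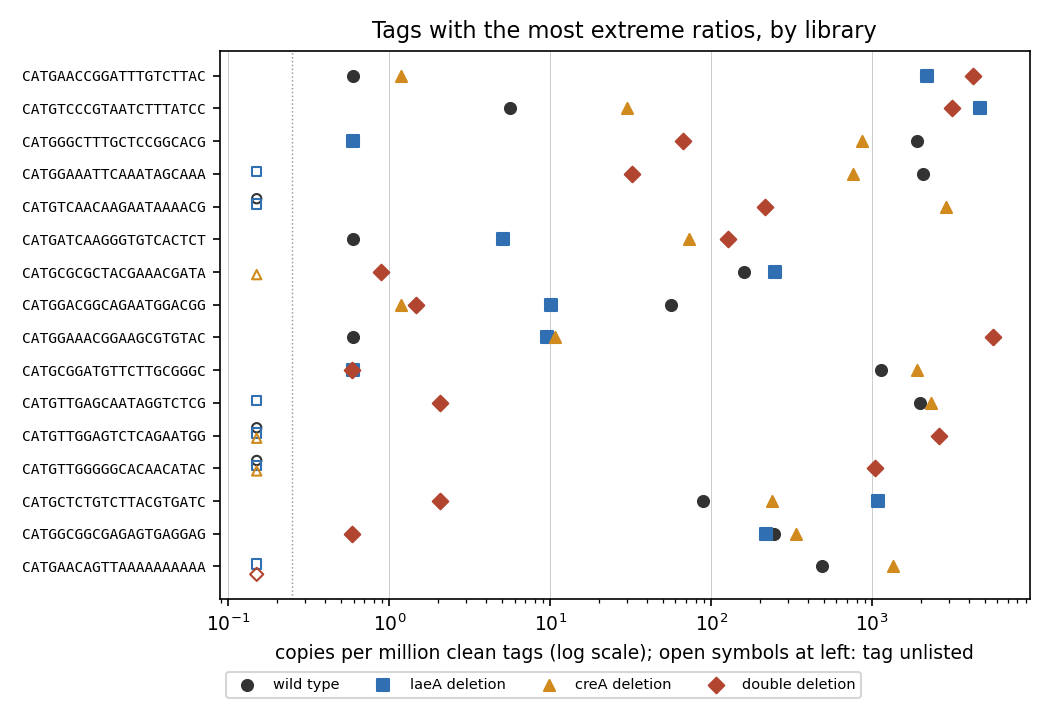
Abundance in copies per 1000000 clean tags (log scale) of the tags with the most extreme ratios in the 5 comparisons, with 1 symbol per library; open symbols at the left stand for unlisted tags. CATGAACCGGATTTGTCTTAC lies at 2185 and 4248 TPM in the libraries without laeA, against 0.593 and 1.19 in those with it.

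Falls in the libraries without laeA coincided with and without creA, again in pairs of libraries with no member in common. In both, 1317 tags fell, 41.6% of those that fell in the laeA deletion, where independent lists would share 511, and 1052 within classes of GC content, trailing A run and abundance in the libraries with laeA. Shared rises were fewer than independent lists would give, 664 against 886. Of the tags that rose in the laeA deletion, 860 were lower in the double deletion than in the creA deletion, against 681 for independent lists, and of those that fell, 401 were higher, against 665. The log2 ratios correlated across tags at Pearson 0.249 and Spearman 0.0852.

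The same contrast was seen in tags that separated the libraries with laeA from those without it, a grouping of the tags made after their values were seen. There were 914 tags 4-fold or more lower in both libraries without laeA than in both with it. They held 11.3% of the wild-type copies and 10.7% of the creA deletion copies, but 0.490% in the laeA deletion and 0.469% in the double deletion. The reverse held for 411 tags. By creA, 61 tags were lower and 47 higher. In the remaining pairing, wild type and double deletion against the single deletions, 102 were lower and 146 higher. Both of these pairings need a 4-fold difference between the wild type and the creA deletion, the most alike libraries. At that threshold, the creA deletion had 457 rises and 501 falls against wild type, and the laeA deletion 2434 and 2342. That similarity limits the counts by creA and in the remaining pairing, so the lower counts do not by themselves single out laeA. Tags with 20 or more copies in both libraries with laeA and unlisted in both without numbered 182. Within such classes, 21.1 were expected from the losses of each library if tags are independent. The 182 included CATGGATTTGGATCTACACAG, with 2573 and 2282 copies in the wild type and the creA deletion. The reverse was found for 48 tags, among them CATGAGAATTATGATGGGAAA, with 1624 copies in the laeA deletion and 445 in the double deletion. By creA, 1 tag was lost, CATGCCGTGCAGCCTCCAAAA, with 46 copies in the wild type and 29 in the laeA deletion, and 6 were gained. One of these, CATGTGTATCACTGGCAAACT, had 277 copies in the creA deletion and 427 in the double deletion.

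**Figure D3:**
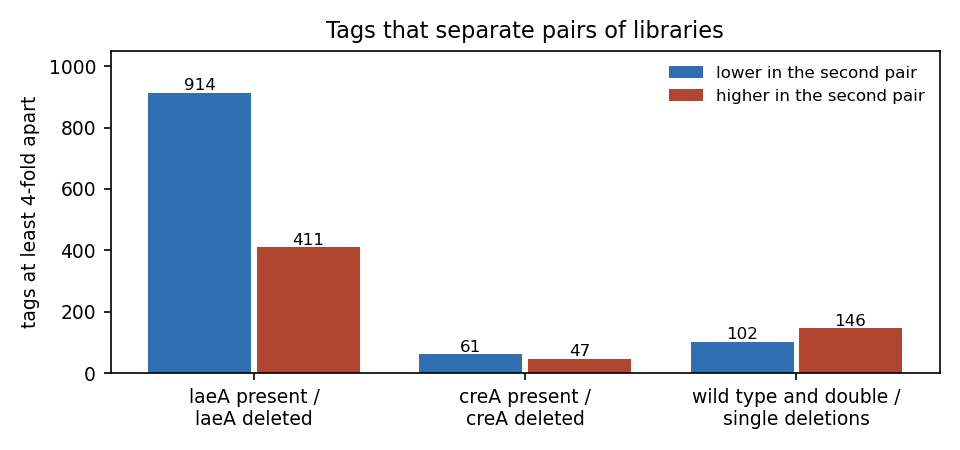
Number of tags 4-fold or more apart between pairs of libraries (vertical axis), for each of the 3 ways to pair the 4 libraries. The division by laeA separates 914 and 411 tags, that by creA 61 and 47, and the remaining one 102 and 146. The divisions other than that by laeA need a 4-fold difference between the wild type and the creA deletion, the most alike libraries, which limits their counts.

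For 8756 tags, 24.9% of the 35219 for which a departure could be computed, the double deletion departed from the sum of the log2 ratios of the single deletions by more than counting error and 2-fold. Of these, 3630 lay above the sum and 5126 below it. CATGACAAGTTCATCATCATT fell in both single deletions, 20.9-fold and 9.69-fold, and rose 11.7-fold in the double deletion, a departure of 11.21 on the log2 scale. CATGAAGTAGTGAGAAAAGAC had 52 copies in the wild type, was unlisted in the laeA deletion, had 3 copies in the creA deletion and 211 in the double deletion, a departure of at least 10.24. CATGCTCTGTCTTACGTGATC rose 12.1-fold in the laeA deletion and 2.65-fold in the creA deletion and fell 43.3-fold in the double deletion, a departure of -10.44. CATGGCTAGCTCCAACGCCGG had 572, 856 and 1595 copies in the wild type, laeA deletion and creA deletion and was unlisted in the double deletion, a departure of -9.65 or lower.

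An additive model over all 4 libraries, in which the departure from additivity serves as the error with 1 residual degree of freedom, called no tag for either gene. The error of each tag was moderated across all tags, with 16.7 prior degrees of freedom. The power of the model at the estimated coefficient of variation of 0.779 was not tested, so the absence of calls does not show an absence of effects. With edgeR's quasi-likelihood test, 3152 tags had an unadjusted p under 0.05 for laeA, where chance gives 1902, and 1263 for creA. The number for creA lay below that of chance, so 1902 is not a firm benchmark here. DESeq2 called 136 tags higher and 407 lower without laeA, and 17 higher and 4 lower without creA.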

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

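The tests of depth, sequence variants and incomplete NlaIII cutting were chosen after the results they bear on had been seen, although the thinning itself had been planned; those of the most abundant tag and GC content were added after the data were seen, but before their own results were.

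The double deletion departed from the sum of the single deletions for 3630 tags in the positive and 5126 in the negative direction, by the exact test of that difference. The tags with the largest departures were CATGACAAGTTCATCATCATT at 11.21, CATGAAGTAGTGAGAAAAGAC at 10.24 as a bound, CATGCTCTGTCTTACGTGATC at -10.44 and CATGGCTAGCTCCAACGCCGG at -9.65 as a bound, all on the log2 scale. Every such departure rests on the 1 double deletion library, and they include whatever sets that library apart.

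That library listed more tags, with a flatter distribution, than the other 3. Depth does not account for it, since after thinning to 1 total it listed 1.315 times the tags of the laeA deletion; nor does the leading tag or GC content alone account for its distance from the wild type, since 100.3% of the number of calls was left without that tag and 97.6% after GC centring. Another strain's sequence variants were also not found, with a partner 1 base away for 0% of 56 lost tags (upper 95% limit 6.38%). Incomplete NlaIII cutting is a candidate source of part of the extra tags, since the share of copies with a second CATG was 2.21 times the highest of the others. Whether it also altered abundant tags stays open, as do the genotype, the culture and other steps of preparation in this 1 library, since the interquartile range of log2 ratios of the 500 most abundant wild-type tags was 2.66, but also 2.86 in the laeA deletion, which had the lowest share with a second CATG.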

How the results depend on the processing

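The alternatives of the most abundant tag, unlisted tags, merged neighbours and the filter without the double deletion were chosen after the results were seen. Of the counts of calls, 51 recomputed values lay within 1.5 times the reported ones and 18 did not. Both numbers include counts of edgeR's exact test, made at a looser adjusted p than those of the main test. All 48 values of named tags and of tags listed per library stayed on the same side. The majority direction of calls turned under settings given in the results and below; for the double deletion against the laeA deletion, at 50.7% rises, it also turned without tags under 5 copies (49.0%) and with a coefficient of 0.2 (49.2%), and the cause was not tested. A minimum of 100 copies, which tests fewer tags, gave 4719 calls for the laeA deletion against wild type, 7345 for the double deletion against wild type, 7810 against the laeA deletion and 7631 against the creA deletion, and in these last 3 the share of rises was 46.6%, 43.3% and 45.8%. With an assumed coefficient of variation of 0.4, edgeR's exact test gave 2587, 69, 7713, 8555 and 9015 calls. The order is laeA deletion, creA deletion and double deletion against wild type, then double against laeA and creA deletion. In that order, a coefficient of 0.2 gave 8083, 1620, 16056, 17687 and 17642 calls. Apart from 1620, these exceed the counts of the main test. This test called tags at an adjusted p under 0.05, against at most 0.001 in the main test, so it differed in more than the spread. Its counts are thus not the part of the main calls that withstands added spread. At 0.4 the share of rises for the laeA deletion was 43.6%. A threshold of 4-fold left 4776 calls for the laeA deletion, 958 for the creA deletion and 427 shared by both. In the additive fit, DESeq2 called 543 tags for laeA and 21 for creA, no filter 208 and 1, and no TMM factors 140 for laeA, where the edgeR fit reported called 0; the cause was not tested. Alternatives that need genes (totals of assigned tags, the 3'-most site, no downstream extension, gene list medians) were not run. No paired analysis was possible because each strain had 1 library and so no replicate numbers to pair; the additive fit sets each gene within both backgrounds of the other. Depth limits the listing of tags near 1 copy per library, and the missing replicates limit every count of calls.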

Other observations

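The class-matched overlaps by abundance over the 4 libraries were chosen after the data were seen, but before their own results were, and those by abundance in the libraries that still had the gene, the coincidence of unlisted tags and the search for tags of the creA gene were tests chosen after the results were seen.

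The 500 most abundant wild-type tags were lowered to different extents in the 3 deletion libraries. The laeA deletion had 157 of them 4-fold or more lower and 6 higher, with a median log2 ratio of -0.87. The creA deletion had 26 lower and 1 higher, with a median of -0.28. The double deletion had 213 lower and 16 higher, with a median of -1.57. Chosen instead as the 500 most abundant of the deletion library itself, tags had medians of 0.82 for the laeA deletion, 0.28 for the creA deletion and 1.70 for the double deletion, so the falls are in part set by the choice of tags. Some abundant tags were nearer to the wild type in the double deletion than in both single deletions. CATGTCCGTTTTTGTTCGAAA stood at 8030 TPM in the wild type, 1076 in the laeA deletion, 4516 in the creA deletion and 5456 in the double deletion, and CATGCTAATCGAACGACTAAT at 6040, 2172, 2036 and 3500. Tags with 20 or more copies that were listed in a single library numbered 1012 for the double deletion, where they held 2.07% of its copies, 86 for the laeA deletion, 8 for the creA deletion and 6 for the wild type.

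Losses shared by both libraries without laeA raise the hypothesis of a set of transcripts that depends on laeA with and without creA. Tags lost from the lists of both numbered 182, against 21.1 expected from the 335 and 472 losses, a ratio of 8.63. That expectation was taken within classes of GC content, trailing A run and abundance. Chance coincidence does not account for the 182 if tags are independent. A gene can give several tags, however, and the expectation does not allow for their joint losses. The wider set of 1317 shared falls stays open, since it was 1.74 times the number expected with abundance taken over the 4 libraries, which the falls themselves lower, but 1.25 times with abundance taken in the libraries with laeA. The shared rises were 0.759 and 0.716 times the number expected in these ways. Genotype and library are confounded, and a laeA effect stays open beside any unrecorded trait shared by both libraries.

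Opposite movement after creA loss with and without laeA may come in part from the tag makeup of the double deletion. Within classes of GC content, trailing A run and abundance, the 525 tags higher in the creA deletion and lower in the double deletion than in the laeA deletion were 1.24 times the number expected, and the reverse 399 were 1.17 times. With abundance taken in the libraries with creA, the ratios were 1.23 and 1.73. An interaction of the genes and the makeup of the library cannot be told apart from these values.

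A search for tags of the deleted creA gene itself found 7 tags with 20 or more copies in both libraries with creA and at most 3 in both without, the largest being CATGCGCGCTACGAAACGATA with 536 and 832 copies against 0 and 3. The pairing of wild type and double deletion against the single deletions, which neither gene separates, gave 8 such tags.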
